A study of Mus musculus with 22 samples.

How the data were processed

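RNA was measured in 22 libraries of mouse splenic immature B cells (B220+CD93+), in 7 groups that the labels set by strain, treatment and experiment. RNA was isolated with the RNeasy Plus Micro kit and libraries were made with the SMART-Seq Stranded Total RNA kit, per the labels' protocols. Total RNA libraries keep ribosomal and small RNAs, and Gm23935 took 16.1% to 28.7% of the reads of the libraries of experiment 1. Per the submitters' processing notes, the tools were bcl2fastq and STAR 2.5.2b and the genome was mm10. The read counter, its use of strand, the gene annotation and the method behind the scaling factors are not given in the sources used here.

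The deposited files are 3 tables of normalized counts per gene, a signal that the authors scaled per library, named as normalized counts in the labels. The tables cover experiment 1 (6 libraries, 21880 genes), experiment 2 (10 libraries, 26097 genes) and culture (6 libraries, 25676 genes). Each table was normalized on its own, so levels were compared only within a table and only fold changes were set side by side across tables. All columns of the tables belong to the 22 samples. In each library the values were whole multiples of what 1 read was worth, so that 100% of values gave whole reads within a tolerance of 0.01, and library sizes are sums of these recovered reads. Median-ratio factors recomputed from the deposited values lay between 0.978 and 1.011. Of the gene identifiers, 98.9%, 98.8% and 98.8% of the 3 tables were found in GENCODE M21, from which coordinates (GRCm38) were taken.

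Each comparison was tested with limma (3.58.1, R 4.3.3; lmFit, eBayes with a trend) on log2(value + 1) for genes with a mean of at least 10, with a Benjamini-Hochberg adjusted p under 0.05 and no minimum fold. This left 11701, 13364 and 12386 genes in experiment 1, experiment 2 and culture. Experiment 1 and culture were fitted on their 2 groups. The 3 groups of experiment 2 were fitted together, since 1 of them has 2 libraries, and the 3 comparisons of experiment 2 share libraries. No covariate or replicate block was used. The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. For a gene with 0 reads throughout a group, a bound on its fold was computed against a floor of 3 reads over the group, which covers counting error only.

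At the median tested gene the counting error was 7.05%, 5.37% and 5.88% in experiment 1, experiment 2 and culture, and at a mean of 10 it was 30.8%, 32.7% and 30.1%. All 26 pairs of replicates differed by more than counting error (lowest chi-square per degree of freedom 5.2) with Spearman's rho across genes of 0.968 to 0.993, so no libraries were joined and each was counted as 1 sample, though separate preparations of 1 sample would differ by more than counting error too. Limma was tested on simulated data with the depth and spread per gene of these libraries, where each gene varied on its own. It recovered 72.6% of genes changed 2-fold in the depletion comparison of experiment 1 (11 false calls) and 71.8% in that of experiment 2 (13 false calls). It recovered 63.4% against the toxin control (9 false calls), 78.9% for the toxin control against untreated (7 false calls) and 76.8% in culture (9 false calls). No simulated library departed from its group across many genes at once, as depleted replicate 1 of experiment 1 did. These shares can therefore overstate what the real libraries allow, and they do not explain a low number of called genes.

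The 40 fixed gene lists covered B cell biology (26), other cells that the sort could hold (9) and RNA quality (5). Lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. No list called this way held with an estimated correlation in any comparison. Camera was run with a trend in the variance, a setting that was not fixed before the data were examined. Fry was run beside it. Members were counted after adjustment over all genes and after adjustment over the list alone.

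Genes were named by a fixed rule. It took up to 8 genes with the highest and up to 8 with the lowest log2 fold change among those with an adjusted p under 0.05, groups that do not overlap and a mean of at least 50. Variable, diversity and joining segments, predicted genes, pseudogenes and small RNA genes with symbols that begin with Mir, Snor, n-R, Rn, Rmrp or Rpph were left out, which kept the small RNA gene Scarna6. It added up to 3 genes per list with an adjusted p under 0.05 and the smallest p, and Cd93, Ighd, Cr2, Fcer2a, Il4ra, Tnfrsf8, Xbp1 and Trdc in every comparison. Where fewer than 5 genes met the first part, the 5 with the smallest p were taken, and genes of the first part could be quoted in other comparisons. Genes named outside this rule are said to have been chosen after their values were seen. Tnfrsf8 and Trdc were not among the tested genes and are not analysed here. Some genes taken by the rule are not reported here. Genes with close copies (IgG constant, histone, Gbp, Tgtp and Pira genes) and genes that overlap others on the opposite strand (Rbm3os, Kcnq1ot1) are uncertain, since the counting could have split or joined their reads.

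Fold changes of different tables were compared with Spearman's rho across genes tested in both, against the rho of other splits of the libraries, all 210 or 100 pairs of splits that could be made, and so were the lists called in both depletion comparisons, after the result had been seen. Alternatives were other pseudocounts, filters on low genes, quantile normalization, recomputed factors, a robust fit, edgeR (4.0.16) and DESeq2 (1.42.0) on the recovered reads, a replicate block, other groups in the fit, and leaving out each library in turn. The T cell transcript level and the sex of the mice as terms, and camera without the trend, were added after the data had been seen.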

Results

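The series measured the transcriptome of splenic immature B cells, sorted as B220+CD93+, in the presence and absence of gamma delta T cells. It holds 22 libraries of total RNA in 7 groups. In the spleen experiments, Tcrd-GDL mice were left untreated or were given diphtheria toxin, 2 injections of 15 ng per g body weight 48 h apart, and cells were taken 8 days after the first injection. According to the series design, the toxin removes gamma delta T cells from these mice. Experiment 1 had 3 untreated and 3 depleted libraries. Experiment 2 had 5 untreated and 2 depleted libraries and 3 libraries from toxin-treated Tcrd-H2BeGFP mice, here called the toxin control, a strain for which the labels do not state whether it carries a toxin receptor. In culture, immature B cells of untreated Tcrd-H2BeGFP mice were kept alone (3 libraries) or with gamma delta T cells (3 libraries). The libraries held 9794413 to 20343954 reads in experiment 1, 22022330 to 36840455 in experiment 2 and 17505909 to 28729574 in culture. Values are normalized read counts given as mean ± SD. Fold changes are on the log2(value + 1) scale ± SE, a scale that understates the change of low genes. Adjusted p-values are from limma with Benjamini-Hochberg adjustment over all tested genes unless a list test is named. The labels do not say how the libraries of a group relate to each other, so the p-values measure the spread between these libraries.

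Experiment 1 asked whether immature B cells differ 8 days after the first toxin injection from those of untreated mice. By the rule for named genes, the genes with the lowest p were Nlrc3, a NOD-like receptor family member, at 235 ± 35.5 against 100.3 ± 7.70 in the depleted and untreated groups (3 libraries each, log2 1.21 ± 0.16), Sdc1, which encodes CD138, at 197 ± 30.2 against 405 ± 38.9 (log2 -1.04 ± 0.14), and Trim7 at 883 ± 91.4 against 518 ± 38.1 (log2 0.77 ± 0.11). The adjusted p was 0.181 for each of them, the lowest of the comparison, and Ap1s2 and Pdzd2 followed at 0.329 and 0.391. None of these 5 genes passed the threshold. Of 11701 tested genes, limma called 0 at an adjusted p under 0.05, with 1033 at an unadjusted p under 0.05. The edgeR quasi-likelihood test on the recovered reads also called 0, and DESeq2 called 31. Groups did not overlap for 15.2% of genes, where chance gives 10%.

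As sets, 17 of 33 gene lists fixed before the data were examined stood apart from the other genes in experiment 1 by camera with its preset correlation, 13 of them lower and 4 higher in depleted cells. The list of mitosis genes had a median log2 change of -0.65 (adjusted p 3.36e-06), with 19 of 20 members negative, among them Cenpf at -1.35, Hmmr at -1.09 and Mki67 at -0.45. DNA replication genes had a median of -0.30 and the replication-dependent histone genes of -0.42. The transitional and immature B cell list, which marks the earliest splenic B cells, had a median of -0.33 over 9 genes. In it Rag1, a recombinase gene of developing lymphocytes, was at 21.6 ± 18.5 against 41.6 ± 10.6 (adjusted p 0.555), and the transcription factor gene Myb had a log2 change of -0.79 (adjusted p 0.443). Since no gene passed, members of these lists other than Rag1 and Mki67 were chosen after their values had been seen. Early B cell receptor response genes had a median of -0.24, with Nr4a1 at -0.66 and Egr2 at -0.65. The MHC class II list had a median of 0.18, with 12 of 13 members positive. The ribosomal protein list had a median of 0.12 (0.0539 with quantile normalization), with 39 of 41 positive. The remaining lower lists were ribosome biogenesis and MYC target genes (median -0.15), B-1 and atypical B cell genes (-0.48), type I interferon response genes (-0.23), interferon gamma response genes (-0.15), IL-4 and STAT6 response genes (-0.19), unfolded protein response genes (-0.09), immediate early and heat shock genes (-0.11) and macrophage and monocyte genes (-0.35). The marginal zone list (median 0.27) and the sex-linked genes (4.73) were higher. Of the depleted mice 1 was male, and depleted replicate 2 also held reads of Y-linked genes. No member of any list passed the test over all genes. Adjusted over the list alone, 2 members passed as lower in the transitional list and 1 each in the ribosome biogenesis, B-1, macrophage, IL-4, immediate early and unfolded protein response lists. The interferon gamma list had 1 higher and 2 lower, the MHC class II and marginal zone lists 1 higher each and the sex-linked genes 4 higher, and the other 6 lists had 0. None of the 17 calls held with an estimated correlation, where the adjusted p was 0.4 for the early B cell receptor, MHC class II, B-1, sex-linked, transitional and IL-4 lists and 0.685 for the other 11. The common T cell list had a median of -0.47 (adjusted p 0.0537), and Lyz2, a myeloid marker, a log2 change of -1.52 (adjusted p 0.502).

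The libraries of experiment 1 were not alike. Depleted replicate 1 came from a male mouse by its sex-linked genes (Xist 3.06, Ddx3y 569), whereas the untreated libraries had no reads of Ddx3y. Depleted replicate 2, with Xist at 9866, held the Y-linked genes Ddx3y at 40, Eif2s3y at 21.1, Kdm5d at 32.6 and Uty at 16.8. The source of these reads was not tested. The Rag1 value of depleted replicate 1 was 42.8, against 13.7 and 8.42 in depleted replicates 2 and 3. It was 32.7 to 53.4 in the untreated libraries, a gene picked here after its values had been seen. Depleted replicate 1 also gave 28.7% of its reads to Gm23935, against 16.1% to 20.4% in the other 5 libraries. Without this library limma called 1092 genes, 477 higher and 615 lower in depleted cells.

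In experiment 2 the depleted group had lower values of Rag1 and Mki67 and higher values of Ddit4, Fkbp5 and Tsc22d3 than the untreated group (2 and 5 libraries). Rag1 was at 44.3 ± 11.5 against 189 ± 74.3 (log2 -1.99 ± 0.30, adjusted p 0.013) and the proliferation marker Mki67 at 62.2 ± 27.5 against 177 ± 40.5 (log2 -1.53 ± 0.28, adjusted p 0.0288). Ddit4, an inhibitor of mTORC1, stood at 1674 ± 879.6 against 415 ± 138 (log2 1.96 ± 0.28, adjusted p 0.00957). Fkbp5, an FK506-binding protein induced by glucocorticoids, stood at 656 ± 285 against 235 ± 45.6 (log2 1.43 ± 0.23), and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, at 13525 ± 4538 against 7043 ± 1223 (log2 0.92 ± 0.17). Both depleted libraries lay on the same side of all 5 untreated libraries for each of these genes. The rule for named genes asked for this of genes taken by their fold change, so it adds no support. Limma called 40 of 13364 genes, 17 higher and 23 lower, 22 of them by at least 2-fold, and 1309 genes had an unadjusted p under 0.05. The 10 libraries of the 3 groups shared 1 estimate of the spread. Groups did not overlap for 12.3% of genes, where chance gives 9.52%.

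Among the higher genes, the negative regulators of lymphocyte signalling Ptpn22 (log2 1.17 ± 0.19) and Pik3ip1 (log2 1.17 ± 0.21) passed, as did Ston1 (log2 3.28 ± 0.43), the small RNA gene Scarna6 (log2 1.25 ± 0.25) and Rbm3os (log2 1.23 ± 0.23), an antisense gene whose reads are uncertain because the use of strand in counting is not stated. Ighd, the constant gene of IgD, which follows B cell maturation, was at 18383 ± 4356 against 10637 ± 1157 (log2 0.78 ± 0.13, adjusted p 0.0209), and the survival gene Bcl2 had a log2 change of 0.60 ± 0.12. Lower genes included Arhgap10 (log2 -1.47 ± 0.26), Agbl1 (log2 -1.45 ± 0.27), Uchl1 (log2 -1.41 ± 0.27), the histone gene Hist1h3b (log2 -1.05 ± 0.21), which has close copies, Ap1s2 (log2 -0.91 ± 0.18), Eaf2 (log2 -0.89 ± 0.18) and the kinase gene Pim1 (log2 -0.69 ± 0.13). Gpr183, an oxysterol receptor that positions B cells in the spleen, was at 1016 ± 119.5 against 1579 ± 139 (log2 -0.64 ± 0.11, adjusted p 0.0209). In the toxin control group Gpr183 stood at 1011 ± 45.0, a log2 difference of 0.00 ± 0.12 from the depleted group (adjusted p 0.99, looked up after the value had been seen). The sorting marker Cd93 (1141 ± 65.7 against 1188 ± 192), Cr2 (6980.1 ± 431 against 7344 ± 1159), Fcer2a (5663 ± 1258 against 5482 ± 418), Il4ra (6056 ± 926 against 5954 ± 140.3) and Xbp1 (1586 ± 267 against 1794 ± 179) did not pass the test.

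**Figure D1:**
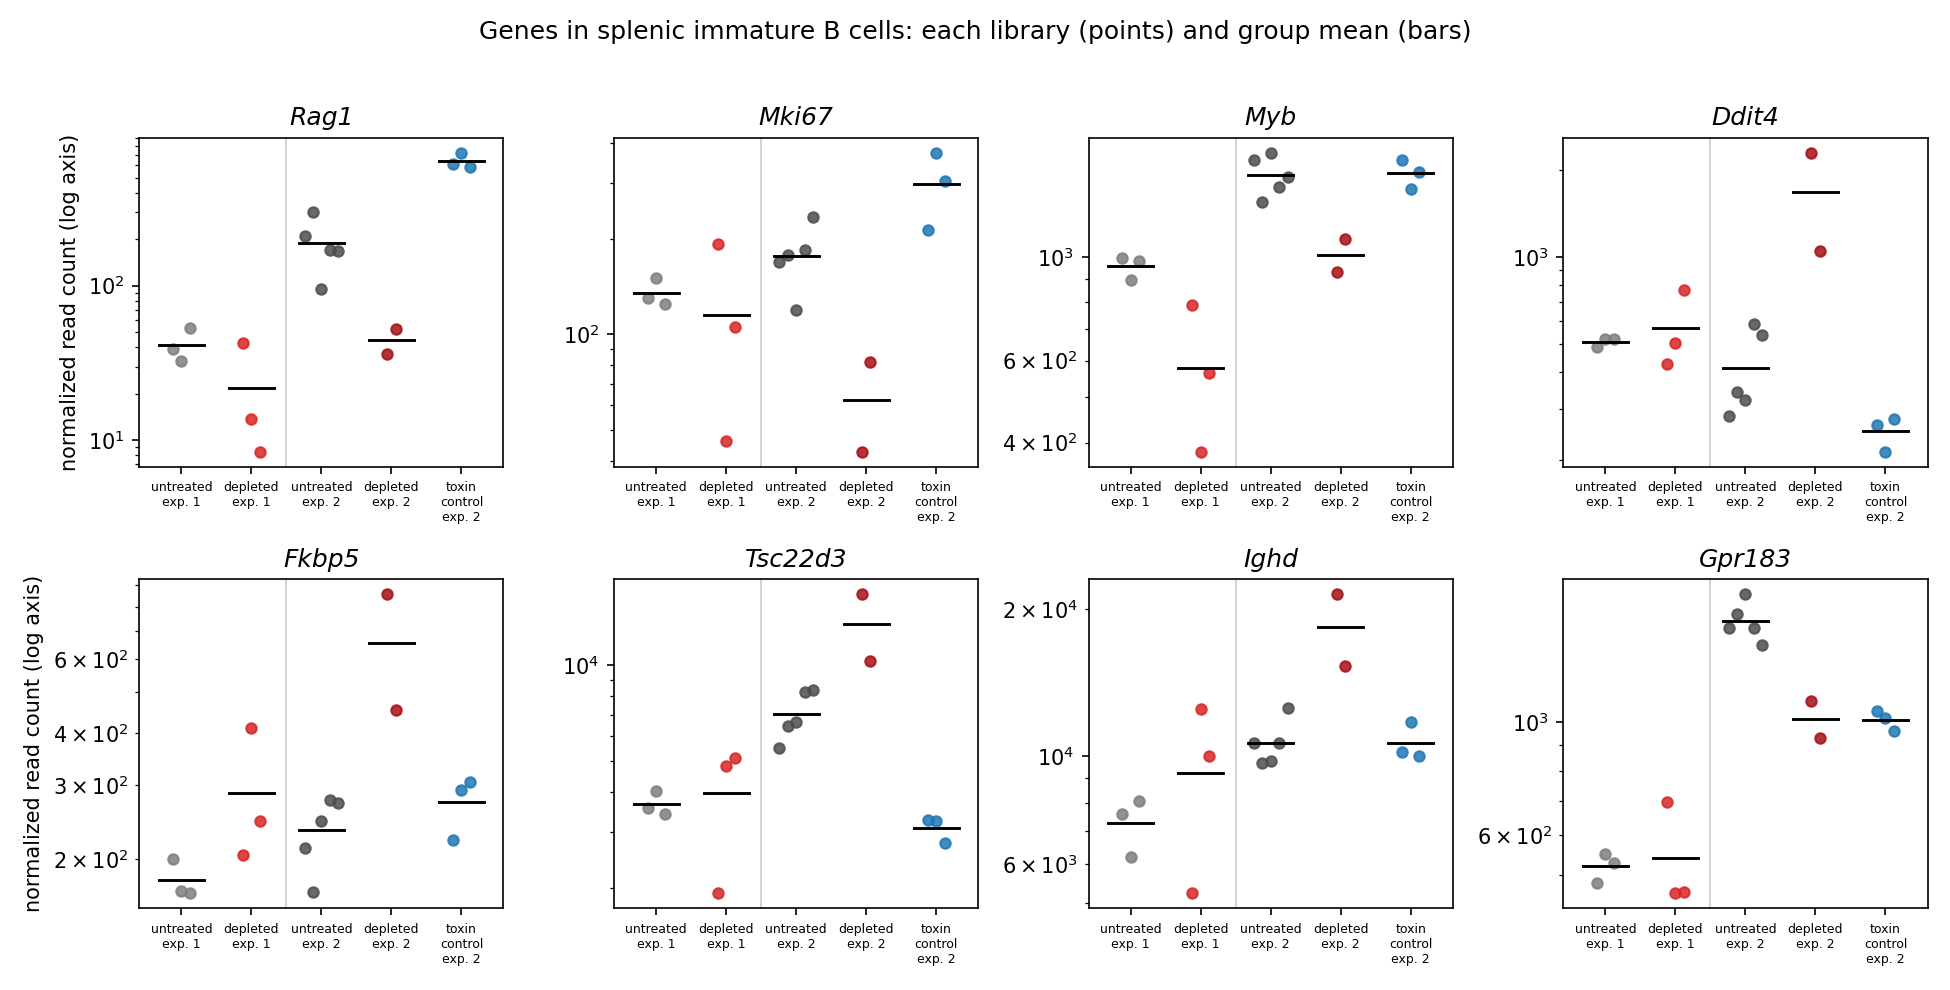
Normalized read counts of 8 genes in each spleen library on a log axis, by group, with bars at the group means. Levels are comparable only within an experiment. Genes named by their fold change were required to have groups that do not overlap. In experiment 2 both depleted libraries lie below all 5 untreated libraries for Rag1, Mki67 and Myb and above them for Ddit4, Fkbp5, Tsc22d3 and Ighd, while the Gpr183 means are 1016 ± 119.5 in depleted, 1011 ± 45.0 in toxin control and 1579 ± 139 in untreated libraries (± SD).

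By list, 10 of 36 stood apart in experiment 2 by camera with the preset correlation, 7 lower and 3 higher. Type I interferon response genes had a median of -0.28 (adjusted p 6.03e-07), with 24 of 27 members negative, 0 passing over all genes and 4 passing as lower when adjusted over the list alone. Mitosis genes had a median of -0.69, with 17 of 20 members negative, where Mki67 was the 1 member called over all genes and 4 passed adjusted over the list alone. In the transitional list (median -0.34, 9 of 11 members negative) Rag1 and Myb (log2 -0.57 ± 0.11, adjusted p 0.0403) fell and the other 9 did not pass. Adjusted over the list alone 5 passed. In the unfolded protein response list (median -0.12) the chaperone gene Sdf2l1 fell by 0.73 on the log2 scale (adjusted p 0.0434) and 4 members passed adjusted over the list alone. DNA replication (-0.17), early B cell receptor response (-0.16) and p53 target genes (-0.32) were the other lower lists, with 0 members passing over all genes and 5, 1 and 4 passing as lower adjusted over the list alone, where 1 p53 target gene was also higher. Ribosomal protein genes (0.16, or 0.0552 with quantile normalization), MHC class II genes (0.16) and dendritic cell genes (1.00, 8 genes, including Siglech at 2.25 and Flt3 at 1.37, picked after their values had been seen) were higher, with 0 members passing over all genes and 0, 0 and 2 adjusted over the list alone. With an estimated correlation no list passed. The adjusted p was then 0.442 for all 7 lower lists, 0.557 for the dendritic cell and MHC class II lists and 0.739 for the ribosomal protein list. The common T cell list had a median of -0.04 (adjusted p 0.869) and the macrophage list of 0.29 (adjusted p 0.247). Only 2 neutrophil genes were tested, too few for the list test, S100a8 at -2.90 ± 1.02 and S100a9 at -2.59 ± 0.77 (adjusted p 0.309 and 0.205), and both, named after their values had been seen, passed as lower adjusted over the list alone. Untreated replicate 8 had T cell transcripts at a mean log2 level of 7.02, against 5.08 to 5.73 in the other untreated libraries.

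Without depleted replicate 4, 8 lists were called in experiment 2, and of the 10 only the transitional, unfolded protein response, mitosis and DNA replication lists were among them, while the type I interferon and ribosomal protein lists changed direction and did not pass. The number of called genes also rested on single libraries. It was 0 without depleted replicate 4 and 579 without depleted replicate 5, fits in which the lone depleted library is assumed to vary like the other groups, and 8, 18, 19 and 22 without untreated replicates 4, 5, 6 and 7. It was 5 when only the 2 groups compared were fitted, 1 with both control groups pooled, 88 with the T cell transcript level as a term, 137 by DESeq2, and 51 by edgeR, which put 70.6% of its calls higher where limma put 42.5%.

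The depletion effects of the 2 experiments, measured on different libraries, were compared gene by gene. Across the 11687 genes tested in both, Spearman's rho of the log2 fold changes was 0.38, and 63.7% of genes had the same sign. Genes are not independent replicates, so the rho was set against all 210 pairs of splits of the libraries that could be made, of which 3, the real pair included, gave a rho as far from 0. Of 32 lists tested in both experiments, 8 were called in both and all 8 had the same direction, though with an estimated correlation none passed in either experiment (adjusted p 0.4 to 0.685 in experiment 1 and 0.442 to 0.739 in experiment 2). Over the 210 pairs of splits, 4, the real pair included, had as large a difference between the numbers of lists called in the same and in opposite directions, the largest of the others being 11, by a test chosen after the result was seen. The 8 lists were mitosis, DNA replication, type I interferon, early B cell receptor, transitional and unfolded protein response genes, all lower, and MHC class II and ribosomal protein genes, both higher. Only 4 of the 8 stayed called in experiment 2 without depleted replicate 4, and 5 in experiment 1 without depleted replicate 2. The rho fell to 0.0574 without depleted replicate 4 of experiment 2, and was 0.259 without depleted replicate 2 of experiment 1. Against the toxin control the rho was 0.278, a value that 13 of the 100 pairs of splits reached, and it was 0.137 without depleted replicate 1 of experiment 1 and 0.0963 without depleted replicate 4 of experiment 2.

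**Figure D2:**
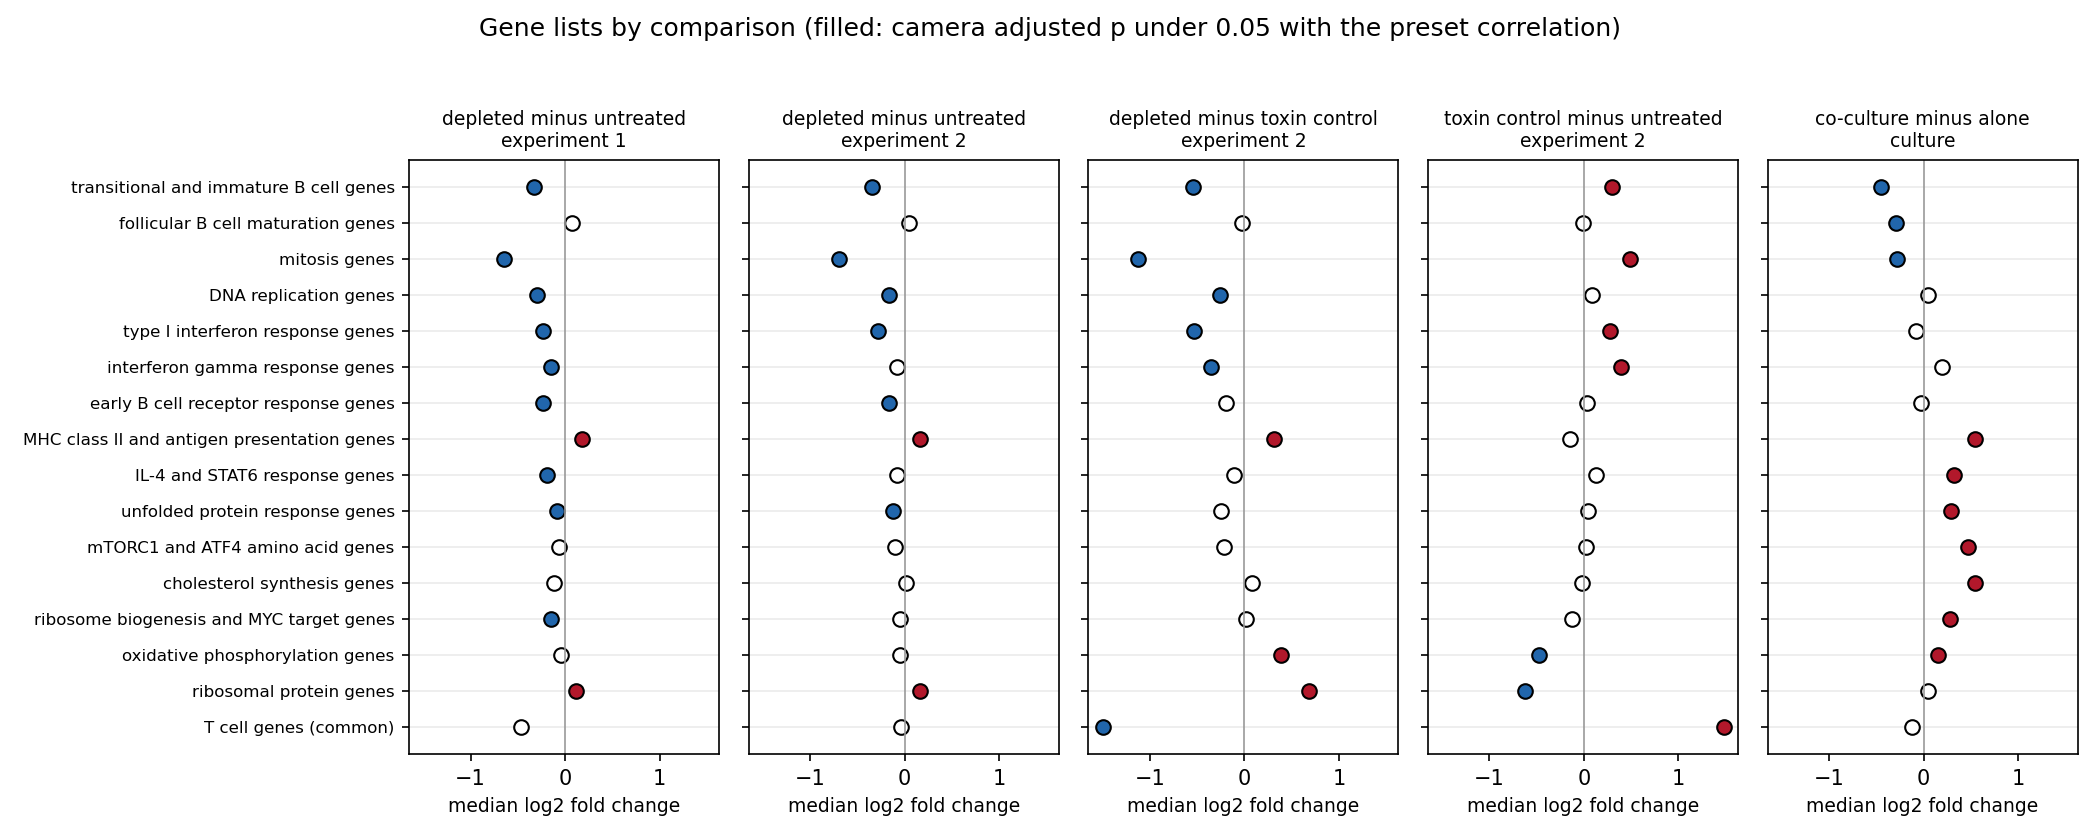
Median log2 fold change (horizontal axis) of 16 gene lists in the 5 comparisons, where filled points, red for higher and blue for lower, have a camera adjusted p under 0.05 with the preset correlation and no list passed with an estimated one. Mitosis genes have medians of -0.65 and -0.69 for depletion in the 2 experiments, and the common T cell list has medians of -1.50 and 1.48 in the comparisons with the toxin control.

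The comparison of depleted with toxin control libraries held the toxin constant but not the strain (2 and 3 libraries). Rag1 was at 44.3 ± 11.5 against 639 ± 76.5 (log2 -3.84 ± 0.33, adjusted p 9.38e-06) and Mki67 at 62.2 ± 27.5 against 297 ± 80.0 (log2 -2.27 ± 0.30). Tsc22d3 stood at 13525 ± 4538 against 3099 ± 281 (log2 2.09 ± 0.19, adjusted p 1.37e-05), Ddit4 at 1674 ± 879.6 against 251 ± 33.7 and the chemokine receptor gene Cxcr4 at 7391 ± 4093 against 1678 ± 152 (log2 2.02 ± 0.28). Cd93 was lower in depleted cells, at 1141 ± 65.7 against 2082 ± 286 (log2 -0.86 ± 0.16, adjusted p 0.00597). Limma called 1212 of 13364 genes, 612 higher and 600 lower, 346 by at least 2-fold. Groups did not overlap for 42.1% of genes, where chance gives 20%.

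By list, 15 of 36 stood apart with the preset correlation, 4 higher and 11 lower in depleted cells, and markers of other cells were among them. The common T cell list had a median of -1.50 in depleted against toxin control libraries (adjusted p 4.06e-06), with 4 of 14 members called lower, Tcf7 at 78.3 ± 16.2 against 328 ± 48.6 among them, and 12 adjusted over the list alone. The alpha beta T cell list (-1.34, 1 of 8 called, Cd28, and 2 adjusted over the list alone), the NK cell and cytotoxic list (-1.47, 1 of 9 called, Nkg7, and 3 adjusted over the list alone) and the myeloid gene Lyz2 (192 ± 69.9 against 662 ± 176) were lower as well. The neutrophil genes S100a8 and S100a9 had log2 changes of -2.33 ± 1.12 and -2.60 ± 0.84 (adjusted p 0.192 and 0.0612), and S100a9 passed adjusted over the list alone. Beside these, the transitional list (median -0.54) had 7 of 11 members lower, with Sox4 at a log2 change of -0.66 ± 0.13, and 8 adjusted over the list alone. The mitosis list (-1.13) had 9 of 20 lower, with Top2a at -1.59 ± 0.30 and Kif11 at -1.97 ± 0.37, and 14 adjusted over the list alone. The type I interferon list (-0.54) had 9 of 27 lower, with Zbp1 at -0.80 ± 0.15, and 14 adjusted over the list alone. Interferon gamma response genes (-0.35, with Gbp6, which has close copies, at -1.33 ± 0.28), B cell receptor signalling genes (-0.25, with Cd81 at -0.72 ± 0.12), DNA replication genes (-0.25), B-1 and atypical genes (-0.54, with Cd5 at -1.88 ± 0.45) and plasmablast genes (-0.31, with Derl3 at -1.39 ± 0.37) were also lower. These lists had 4, 5, 2, 3 and 2 members called lower, and 7, 9, 4, 3 and 6 adjusted over the list alone. Cd81 lies within 1 Mb of Tnfrsf26, a gene without reads in the toxin control group. It was 0.57 ± 0.10 higher on the log2 scale in toxin control than in untreated libraries. Higher in depleted cells were ribosomal protein genes (median 0.68, or 0.362 with quantile normalization, 39 of 41 members called, 40 adjusted over the list alone), oxidative phosphorylation genes (0.39, 10 of 29 called, 20 adjusted over the list alone), MHC class II genes (0.31, or 0.0615 with quantile normalization, 4 of 14 called, with H2-Aa at 0.70 ± 0.16, and 8 adjusted over the list alone) and replication-dependent histone genes (0.61, 3 of 17 called higher and 1 lower, 10 and 2 adjusted over the list alone). With an estimated correlation none of the 15 lists passed. The adjusted p was then 0.383 for the plasmablast, 0.389 for the alpha beta T cell, 0.401 for the NK cell, 0.416 for the histone and 0.358 for each of the other 11 lists.

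Single libraries also moved this count, which was 42 without depleted replicate 4, 2712 without depleted replicate 5, 236 without toxin control replicate 2 and 553 without toxin control replicate 3, the first 2 with a lone depleted library assumed to vary like the other groups. It was 442 with only the 2 groups compared in the fit and 725 without the filter on low genes. It was 1 with both control groups pooled, groups that differed from each other at 2093 genes. With the T cell transcript level as a term it was 17, but that level follows the groups here (5.335 and 6.087 in depleted, 6.781 to 7.52 in toxin control libraries). Mitochondrial ribosomal RNA took 26.15% and 34.8% of reads in depleted and 19.6% to 24.5% in toxin control libraries. Whether this difference in library composition bears on the calls was not tested.

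The toxin control group differed from untreated Tcrd-GDL mice in both strain and toxin (3 and 5 libraries). Tnfrsf26, a TNF receptor family gene, had no reads in the 3 toxin control libraries and was at 261 ± 27.9 in untreated ones, at least 283-fold lower against a floor of 3 reads over the group (adjusted p 1.84e-12). Tnfrsf26 was at 199 ± 35.3 in depleted libraries, at least 215-fold above the same floor. Rag1 rose to 639 ± 76.5 from 189 ± 74.3 (log2 1.84 ± 0.26, adjusted p 0.00187) and Cd93 to 2082 ± 286 from 1188 ± 192 (log2 0.81 ± 0.13). Transcripts of switched immunoglobulin constant genes were higher, with Ighg2b at 1724 ± 874 against 374 ± 386, Ighg2c at 1846 ± 629 against 289 ± 277 and Ighg3 at 1590.2 ± 2320.1 against 84.1 ± 70.0, genes with close copies between which reads can be split. Limma called 2093 of 13364 genes, 978 higher and 1115 lower, 197 by at least 2-fold. Groups did not overlap for 23.4% of genes, where chance gives 3.57%.

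T cell transcripts were higher in this group too. The common T cell list had a median of 1.48 (adjusted p 8.77e-07), with 10 of 14 members called, including Lat at 123 ± 29.8 against 39.0 ± 20.9 and Skap1 at 134 ± 31.9 against 45.9 ± 30.4, of which untreated replicate 8 held 99.87, and 12 adjusted over the list alone. The alpha beta T cell list (1.18, 2 of 8 called, Cd4 at 101 ± 27.3 against 44.8 ± 32.1, 7 adjusted over the list alone) and the NK cell list (1.26, 1 of 9 called, 2 adjusted over the list alone) went with it. Among B cell lists, the transitional list (0.29, 3 of 11 called), mitosis (0.48, 2 of 20, Top2a at 0.94 ± 0.24), type I interferon (0.27, 7 of 27), interferon gamma (0.39, 5 of 19, Gbp5 at 0.47 ± 0.11), B cell receptor signalling (0.15, 5 of 22), B-1 and atypical (0.54, 2 of 10) and immunoglobulin constant genes (2.16, 4 of 9) were higher. Adjusted over the list alone, these lists had 5, 1, 7, 5, 7, 2 and 4 members higher. Ribosomal protein genes (median -0.62, or -0.347 with quantile normalization, 39 of 41 called), oxidative phosphorylation genes (-0.47, 22 of 29, Cox7b at -0.62 ± 0.11), replication-dependent histone genes (-0.48, 5 of 17) and immediate early genes (-0.27, 6 of 13, Fosb at -0.99 ± 0.19) were lower, with 40, 25, 11 and 6 members passing as lower adjusted over the list alone. With an estimated correlation none of these 14 lists passed. The adjusted p was then 0.606 for the mitosis, NK cell and B-1 lists, 0.742 for the type I interferon list and 0.511 for the other 10. This comparison shares its toxin control libraries with the comparison of depleted and toxin control libraries and its untreated libraries with the depletion comparison of experiment 2, so opposite changes between them are not independent.

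Without toxin control replicate 2 the count was 196, without toxin control replicate 3 it was 812, and without untreated replicates 5, 6 and 7 it was 1298, 1008 and 1233. With the T cell transcript level as a term, which in these libraries follows the groups, 7 genes were called. Library composition followed the groups too. Mitochondrial ribosomal RNA took 19.6% to 24.5% of reads in toxin control libraries, against 28.2% to 35% in untreated ones. The 10 genes with the highest mean took 38.0% to 43.4%, against 46.2% to 55.3%. Whether this bears on the called genes or on the ribosomal protein and oxidative phosphorylation lists was not tested.

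Tnfrsf26 lies on chromosome 7 at 143607659 to 143628722 in GRCm38, the assembly that mm10 also names, and is transcribed from the minus strand. Its neighbours within 1 Mb were examined after this result had been seen. Of the 17 tested genes there other than Tnfrsf26, 8 were called, 47.1% against 15.6% of the tested genes outside the region (2-sided Fisher's exact test, p = 0.00229). Tspan32 (log2 -1.53 ± 0.09), Tnfrsf22 (-2.15 ± 0.33) and Mrgpre (-1.83 ± 0.23) were lower like Tnfrsf26, and Shank2 (3.43 ± 0.45), Trpm5 (1.31 ± 0.24), Osbpl5 (0.59 ± 0.09), Cd81 (0.57 ± 0.10) and Kcnq1ot1 (0.54 ± 0.12), which is antisense to Kcnq1, were higher. Mrgpre was at 394.3 in untreated replicate 8, against 296.5 to 318 in the other untreated libraries. Over 1923 windows of 1 Mb along the genome, the window from 143000001 to 144000000 on chromosome 7 had the lowest p for called genes of at least 2-fold, 5 of 15 with Tnfrsf26 among them (adjusted p = 0.00337 by 1-sided Fisher's exact test), where the next, on chromosome 12 from 113000001 to 114000000, with 5 of 41, reached an adjusted p of 0.308.

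**Figure D3:**
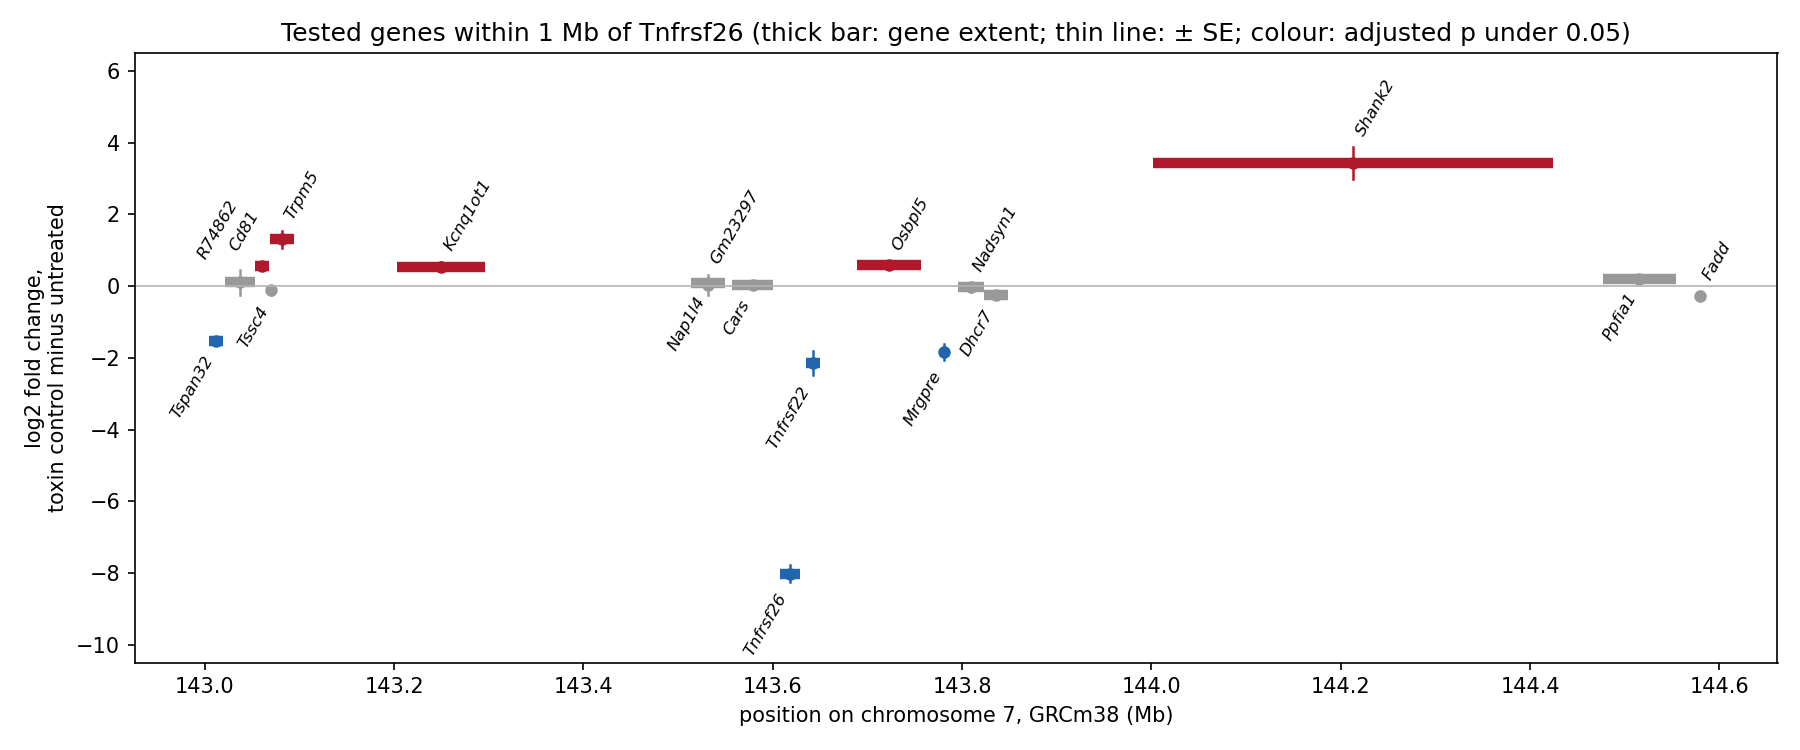
Log2 fold change (vertical axis) of toxin control against untreated libraries by position in Mb on chromosome 7 (GRCm38) for the 18 tested genes within 1 Mb of Tnfrsf26, with thick bars for gene extents, thin lines for ± SE and colour for an adjusted p under 0.05. Tnfrsf26 lies at -8.02, a fitted value that depends on the pseudocount since the toxin control libraries had no reads, and Shank2 at 3.43.

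Culture asked how immature B cells differ when gamma delta T cells are present (3 libraries each). Nfil3, a transcription factor gene induced by IL-4, was at 401 ± 37.8 against 16.5 ± 4.92 with and without gamma delta T cells (log2 4.56 ± 0.23, adjusted p 3.04e-07). The cytokine receptor gene Lifr was at 1278 ± 328 against 103 ± 20.4 (log2 3.61 ± 0.19), Samsn1, an adaptor that restrains B cell activation, at 4901 ± 582 against 684 ± 40.1 (log2 2.83 ± 0.12), and the activation marker Cd83 at 7390.1 ± 237 against 1649 ± 113 (log2 2.17 ± 0.11, adjusted p 4.5e-07). Sdc1 fell to 142 ± 32.8 from 484 ± 58.9 (log2 -1.78 ± 0.17, adjusted p 0.000107) and Apoe to 2343 ± 384 from 5917 ± 530.2 (log2 -1.35 ± 0.14). Limma called 267 of 12386 genes, 136 higher and 131 lower, 97 by at least 2-fold. Groups did not overlap for 18.4% of genes, where chance gives 10%. Other large changes were St7 (log2 3.24 ± 0.14), B3gnt7 (3.43 ± 0.19), Gadd45g (3.18 ± 0.22), Ryr2 (2.63 ± 0.32) and Serpinb6b (2.52 ± 0.23) among the higher genes and Anxa1 (-1.60 ± 0.25), Rapgef4 (-1.17 ± 0.14) and Faah (-1.16 ± 0.21) among the lower.

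By list, 13 of 35 stood apart in culture with the preset correlation, 8 higher and 5 lower. In the IL-4 and STAT6 response list (median 0.32, adjusted p 1.36e-07) 8 of 13 members did not pass and 5 rose, namely Nfil3, Il4i1 (log2 1.81 ± 0.12), Socs1 (1.70 ± 0.15), Fcer2a, which encodes CD23, at 2473 ± 322 against 836 ± 33.3 (log2 1.56 ± 0.12, adjusted p 2.03e-05), and Il4ra at 3417 ± 239.9 against 2184 ± 72.3 (log2 0.64 ± 0.11). Adjusted over the list alone 6 were higher and 1 lower. All 20 cholesterol synthesis genes had positive changes (median 0.55), 8 rose, with Idi1 at 0.85 ± 0.14, Fdps at 0.75 ± 0.13 and Lss at 0.74 ± 0.12, and 17 passed adjusted over the list alone. In the unfolded protein response list (median 0.29) 9 of 33 rose, with Sdf2l1 at 1.56 ± 0.16, Xbp1, a transcription factor of that response, at 1736 ± 126 against 825 ± 54.5 (log2 1.07 ± 0.12) and Trib3 at 1.24 ± 0.17, and 15 passed adjusted over the list alone. In the mTORC1 and ATF4 amino acid list (0.47) 7 of 24 rose, with the transporter gene Slc7a5 at 0.69 ± 0.11 and Shmt2 at 0.73 ± 0.12, and 12 passed adjusted over the list alone. In the MHC class II list (0.54) all 13 members had positive changes and 5 rose, with Ciita, its transactivator, at 0.98 ± 0.19 and H2-DMa at 0.79 ± 0.12, and 9 passed adjusted over the list alone. Ribosome biogenesis genes (0.28) and oxidative phosphorylation genes (0.15) were higher as sets with 0 members passing, over all genes or adjusted over the list alone.

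The lower lists in culture held genes of B cell stage and traffic. In the transitional list (median -0.45) all 10 members had negative changes and Cd24a, at 5488 ± 1164 against 9387 ± 854, Sox4 (log2 -0.75 ± 0.14) and Myb (-0.52 ± 0.12) fell, with 5 passing adjusted over the list alone. The follicular list (-0.29) had Fcer2a higher and Ccr7 (-0.78 ± 0.12) and Bcl2 (-0.62 ± 0.13) among its lower genes, and 1 higher and 8 lower adjusted over the list alone. The homing list (-0.32) had S1pr3 (1.75 ± 0.16) and Gpr183, at 1599.9 ± 138 against 538 ± 107 (log2 1.59 ± 0.15), higher and 4 members lower, and 2 higher and 8 lower adjusted over the list alone. Mitosis genes (-0.28, 0 of 20 passing either way) and B-1 genes (-0.47, with Cd5 at -0.95 ± 0.21) completed the lower lists. Of the B-1 list 5 were lower adjusted over the list alone. The alpha beta T cell list was higher (median 0.55, adjusted p 0.0398) with 0 of 7 members passing over all genes and 1 adjusted over the list alone, while the common T cell list had a median of -0.12 (adjusted p 0.532). No gene of the gamma delta T cell list reached a mean of 10 in culture or in the spleen tables. With an estimated correlation none of the 13 lists passed. The adjusted p was then 0.0719 for the cholesterol, amino acid, ribosome biogenesis and IL-4 lists, 0.105 for MHC class II, 0.167 for the unfolded protein response, 0.288 for the transitional, B-1 and homing lists, 0.307 for the follicular and alpha beta T cell lists, 0.598 for mitosis and 0.813 for oxidative phosphorylation. By fry, which asks whether a list's genes move one way, 8 of these 13 lists passed, and so did the NF-kB and CD30 pathway list (adjusted p 0.04 by fry and 0.508 by camera). Cd93 (1222 ± 100.4 against 1233 ± 176), Ighd (5986 ± 849 against 5828 ± 990.0) and Cr2 (751 ± 100.1 against 559 ± 36.7) did not pass.

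**Figure D4:**
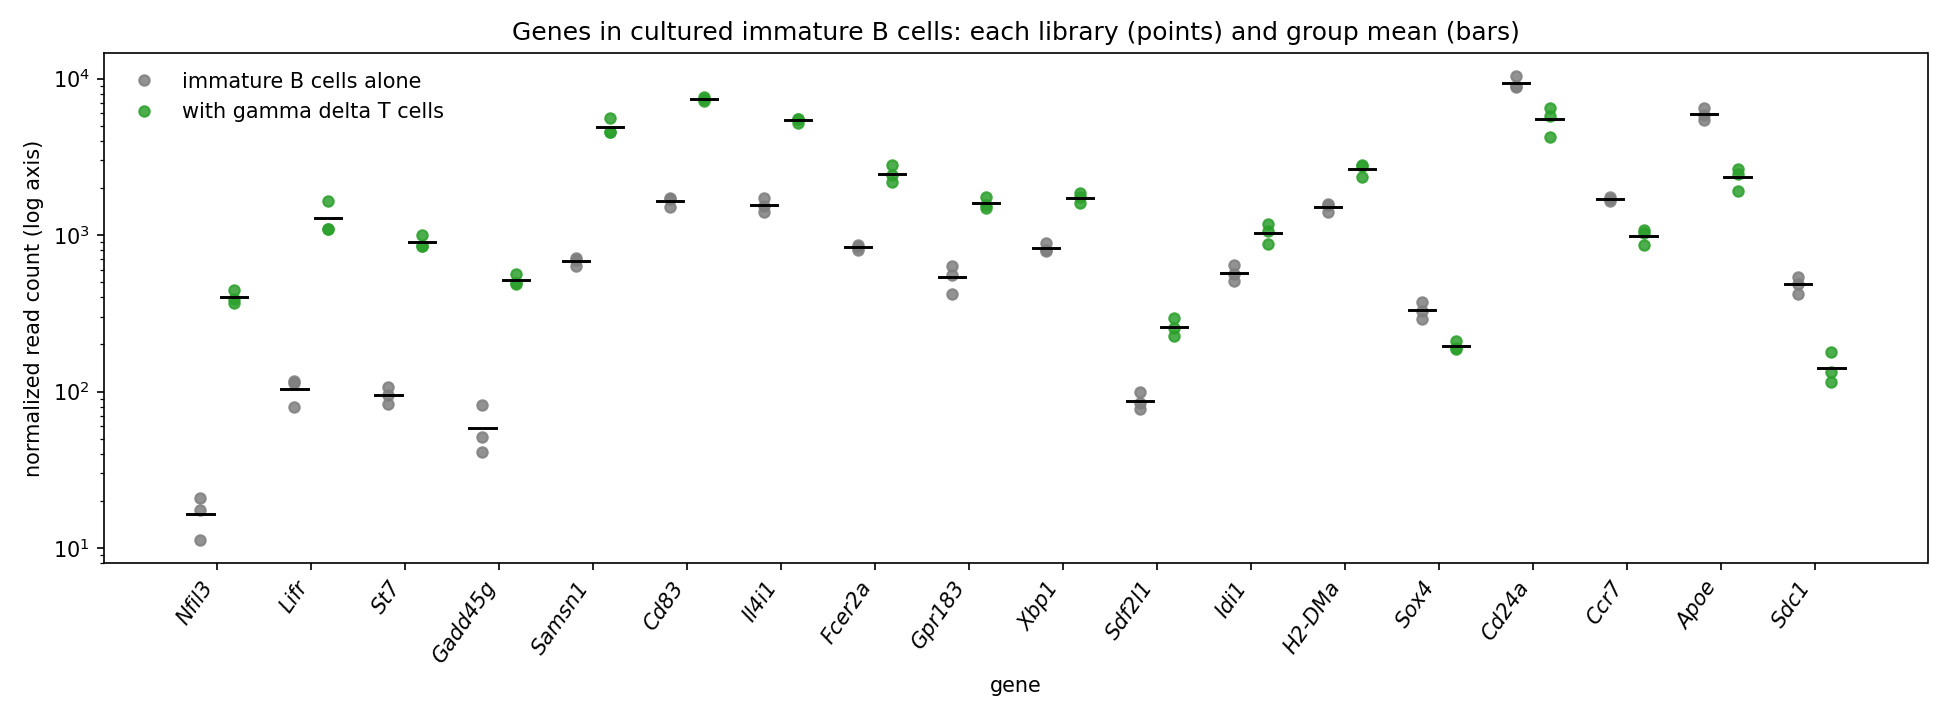
Normalized read counts of 18 genes in the 6 culture libraries on a log axis, with bars at the group means. Grey points are without and green points with gamma delta T cells. Genes named by their fold change were required to have groups that do not overlap. The 3 libraries with gamma delta T cells lie above the 3 without for Nfil3 (401 ± 37.8 against 16.5 ± 4.92 with and without) and Cd83 and below them for Sdc1 (142 ± 32.8 against 484 ± 58.9) and Apoe.

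The culture count was 103, 117 and 110 without replicates 1, 2 and 3 of the cells kept alone, and 166 and 678 without replicates 2 and 3 of the co-culture. Replicate 3 of both culture groups came from male mice by the sex-linked genes, and 545 genes were called with sex as a term.

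Culture and depletion were compared to see whether genes higher with gamma delta T cells in culture were lower after their removal in mice. Across genes, Spearman's rho between the co-culture and the depletion fold changes was -0.0528 for experiment 1 (11483 genes) and -0.0248 for experiment 2 (12233 genes), and 68 of 100 and 167 of 210 pairs of splits gave a rho as far from 0. Among the 12233 genes tested in culture and experiment 2, 265 were called in culture and 38 after depletion. Gpr183 and Sdf2l1 were higher in co-culture and lower after depletion, 2 genes where independent lists give 0.241. Bcl2, Ptpn22 and Pik3ip1 were lower in co-culture and higher after depletion, 3 genes where independent lists give 0.171. Myb was lower in both, 1 gene where 0.236 would be shared, and 0 genes were higher in both, where 0.175 would be. Gpr183 was also low in the toxin control group, at 1011 ± 45.0. The overlaps were not tested. The depletion calls behind them depend on the fit, since 5 genes in all were called with only the 2 groups compared in it.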

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

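The tests of depleted replicate 1 set aside, of a few genes taking the reads, of RNA of other cells in that library, of pairs of splits for culture and experiment 1, of Tnfrsf26 in culture, of strain or toxin, of T cell RNA in co-culture and of the share of males in culture were chosen only after the result was seen.

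In 4 of 48 values tested among the 5 untreated libraries of experiment 2, replicate 8 lay far from the others. Cd3e was at 167.03 there, against 29.2 to 57.2 in the other 4, Lyz2 at 941.04 against 227 to 376.69, Skap1 at 99.87 against 27.44 to 37.49, and Mrgpre at 394.3 against 296.5 to 318. Chance puts about 1 in 20 such groups apart, and here 8.33% were.

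Experiment 1 gave 0 called genes by limma, with 1033 at an unadjusted p under 0.05, 0 by edgeR and 31 by DESeq2. Without depleted replicate 1 limma called 1092, where leaving out any other library of experiment 1 gave 0, so that library being apart may account for the count. For uneven use of reads by a few genes, quantile normalization and recomputed factors both gave a count of 0. The recomputed factors lay between 0.992 and 1.003, so that refit was nearly the reported one and could not decide. Quantile normalization argues only against an uneven scaling of whole libraries, and other effects of such reads stay open. An excess of RNA of T cells or macrophages is argued against by lower levels of both lists in that library than in either other depleted one. The differences in mean log2 from the lower of them were -1.07 and -0.618. Its T cell level of 3.92 was the lowest of experiment 1, where the other libraries had 4.99 to 5.45. It thus also stood apart in such RNA, and whether a lower share of other cells bears on the count was not tested. Sex stays open, as does incomplete removal of gamma delta T cells in that mouse, which was not tested. Spearman's correlation of the deviation of depleted replicate 1 with the male minus female difference in culture was -0.241, under the bound of 0.1 set beforehand, but both male culture libraries are replicate 3, and setting replicates 1 and 2 apart, with no difference of sex, gave 0.231 and 0.0921, so that bound was judged wrong after the value was seen and sex and library cannot be told apart.

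The 6 libraries of experiment 1 allow 10 splits, too few for a share under 0.05. The real split gave 0 genes, as did all 10, and for gene lists 2 of 10 splits gave as many as the real 17, with 20 the highest of the others. In culture the 10 splits are likewise too few. The real split gave 267 genes and the highest other 1 (1 of 10 as large), and for lists 13 and 13 (2 of 10 as large). For the rho between co-culture and depletion in experiment 1, chance cannot be excluded, as 68 of 100 pairs of splits gave a rho as far from 0, with 0.3348 the highest of the others against -0.0528.

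The toxin control group differed from the untreated group at 2093 genes. Chance is argued against for this count, as 1 of 56 splits, the real one, gave as many, the highest of the others being 8. That is the smallest share that 56 splits can give. It also takes the libraries as independent of each other, which the labels do not state. For its 14 lists chance cannot be excluded, since 11 of 56 splits gave as many, the highest of the others being 19. For Tnfrsf26 a strain variant may account for the low values, since the 6 culture libraries, of the toxin control's strain and without toxin, held at most 0.935. For the 2084 called genes outside 1 Mb of Tnfrsf26 strain and toxin cannot be fully told apart, because untreated spleen libraries of that strain are not analysed here. The depleted libraries had the toxin too and differed from the toxin control at 1212 genes, a difference that toxin given to both groups does not explain by itself. These groups also differ in depletion, and how many of the 2084 genes this covers was not counted. The difference in library composition between the groups was not tested as a cause. T cell RNA stays open, since untreated replicate 8, with a T cell level near that of the toxin controls, had a slope of 0.3 along the fold changes of 2080 called genes outside the T cell lists, above the other untreated libraries (-0.282 to 0.0597) but under the 0.5 set beforehand. These genes were called with replicate 8 in the untreated group, which favours genes where it lies near that group. The slope can therefore be too low.

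In culture, RNA of gamma delta T cells carried into the sorted B cells is argued against by the common T cell list. Its median log2 change was -0.121, where the bound set for carried RNA was a rise of 1. By library the mean log2 level of the list was 5.18 to 5.58 in co-culture and 5.33 to 5.61 in cells kept alone. An upper bound of 0.256 on its mean change was taken over the genes of the list. Genes are not independent replicates, so that bound does not measure the spread between libraries. The alpha beta T cell list, however, was higher (median 0.55, adjusted p 0.0398 by camera). In co-culture and alone, Cd3e was at 50.9 ± 6.47 against 46.5 ± 4.79 and Tcf7 at 105 ± 35.7 against 129 ± 9.91. Both groups thus held T cell transcripts although the cells were sorted on B220, so the sort does not argue against carried RNA. Sex of the mice as a difference between the groups is argued against by the equal share of males, 1 library of 3 in each, while a response that differs by sex or replicate number stays open, since a term for sex could not move the fold changes of such balanced groups. A response of the B cells to gamma delta T cells stays a hypothesis, as other differences between the cultures, such as cell density, were not tested, and it was found and tested on the same libraries.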

How the results depend on the processing

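The tests with the T cell transcript level or sex as a term, without the sex-linked genes, of lists without each library, and with camera without a trend were chosen only after the result was seen.

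Where a value moved, the cause was not tested, except that fits on fewer libraries or groups rest on fewer samples. Genes called in experiment 1, 0 in the reported fit, numbered 2 without the filter on low genes, 31 by DESeq2 and 0 to 1092 without each library. The depletion comparison of experiment 2 (40 genes) gave 137 by DESeq2, 5 with its 2 groups alone, 1 with both control groups pooled, 88 with the T cell transcript level as a term and 0 to 579 without each library. Against the toxin control (1212 genes) counts were 725 without the filter, 442 with the 2 groups alone, 1 with pooled controls, 17 with the T cell term and 42 to 2712 without each library. Toxin control against untreated (2093 genes) gave 7 with the T cell term, where Ncr1 reversed to -0.0395 on the log2 scale (adjusted p 0.99), and 196 to 2996 without each library. Co-culture (267 genes) gave 545 with sex as a term and 103 to 678 without each library. Fits that left 1 depleted library assume that it varies like the other groups. The T cell term follows the groups in both comparisons with the toxin control, and the pooled controls join groups that differ at 2093 genes.

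With quantile normalization the median of the ribosomal protein list was 0.0539 and 0.0552 for depletion in experiments 1 and 2, against 0.12 and 0.16, 0.362 against the toxin control, against 0.68, and -0.347 for toxin control against untreated, against -0.619, and that of the MHC class II list against the toxin control was 0.0615, against 0.312. The other called lists kept their median within 1.5 times.

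With an estimated correlation 0 lists were called in each of the 5 comparisons, against 17, 10, 15, 14 and 13 with the preset one. By fry 0 were called for depletion in experiment 1, 0 for depletion in experiment 2, 13 against the toxin control, 0 for toxin control against untreated and 9 in culture. Of the 13 only 8 were among the 15 called by camera, and of the 9 in culture 8 were among its 13. Without each library 13 to 15, 8 to 14, 13 to 18, 10 to 16 and 10 to 17 lists were called, with at least 11, 4, 12, 9 and 9 of the reported ones among them, in the order of depletion in experiments 1 and 2, toxin control, toxin control against untreated and culture. The use of a trend in camera was settled after output had been seen, and camera without one called 6 lists for depletion in experiment 2 and 13, 16, 12 and 13 in the other comparisons, in the order of experiment 1, toxin control, toxin control against untreated and culture.

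Spearman's correlation between the depletion effects ranged from 0.0574 to 0.451 without each library, and with toxin controls from 0.0963 to 0.35. With co-culture, rho was -0.0918 for experiment 1 and -0.0419 for experiment 2 at a mean filter of 50, -0.125 and -0.106 over genes called in co-culture, and -0.0913 to -0.0137 and -0.0381 to -0.00749 without each library. No value over called genes could be had where experiment 1 came first, as it had none.

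Replicate numbers gave no sign of pairing in experiment 1, where the correlations of same-numbered deviations were -0.02, -0.04 and 0.05. In culture they were 0.20, -0.04 and 0.23, and replicate 3 was male in both groups. A pairing by number therefore stays open in culture, and the reported fit did not use it. With the number as a replicate block 0 genes were called in experiment 1, 448 in culture, where replicates 1 and 3 correlated best with their own number and replicate 2 did not, and 153 in the depletion comparison of experiment 2 over libraries 4 and 5, the 2 numbers its groups share.

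Of 4902 values of 273 named gene results, 3890 kept their side of the threshold, of which 36, not called either way, changed sign, while 997 lost the call, 14 gained it and 1 reversed. Called named genes kept in every alternative but single left-out libraries numbered 43 of 50 in culture, 1 of 24 and 0 of 85 for depletion in experiment 2 against untreated and toxin control, and 3 of 85 for toxin control against untreated (Tnfrsf26, Mrgpre and Tspan32). Depth limits genes near the filter, where counting error alone was 30.1% to 32.7% at a mean of 10.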

Other observations

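No test is reported in this part, and the genes named in it were chosen after their values were seen.

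Some genes spread widely between the 2 depleted libraries of experiment 2. Zbtb16, a transcription factor gene, had values of 10.5 and 62.5 in them, against 1.36 ± 1.54 in untreated and 1.56 ± 1.80 in toxin control libraries, and in experiment 1 it was at 6.32 ± 7.59 in depleted and 0.481 ± 0.435 in untreated libraries. In the order of depleted, untreated and toxin control libraries of experiment 2, Sgk1, a kinase gene, was at 715 ± 300.5, 538 ± 49.1 and 417 ± 22.2, Dusp1, a phosphatase gene, at 672 ± 370.3, 391 ± 55.5 and 221 ± 21.7, and Txnip, a regulator of glucose uptake, at 20788 ± 9379, 12936 ± 1055 and 11702 ± 1058. The means of the clock gene Per1 (948 ± 154, 965.7 ± 56 and 949 ± 107) and of Klf9, a transcription factor gene (185 ± 15.9, 173 ± 23.4 and 163 ± 24.8), lay within the spread of the libraries. In depleted and untreated libraries of experiment 1, Sgk1 was at 297 ± 122 and 216 ± 10.2, Dusp1 at 369 ± 135 and 316 ± 66.1, Txnip at 7116 ± 4825 and 5739.8 ± 693, Per1 at 635 ± 204 and 571 ± 77.3, Klf9 at 73.2 ± 7.15 and 66.0 ± 14.9, Fkbp5 at 288 ± 109 and 178 ± 19.5, Pik3ip1 at 805 ± 472 and 487.5 ± 20.51, Ddit4 at 568 ± 181 and 511 ± 18.7, Tsc22d3 at 3968 ± 1769 and 3677 ± 324 and Cxcr4 at 1949 ± 729 and 2573 ± 135.

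In culture Il4, the gene of the cytokine IL-4, was at 0.694 ± 0.635 in cells kept alone and at 0 in co-culture, and Il13 and Ccl1 were at 0 in all 6 libraries. Tcrg-C1, a gene of the gamma delta T cell receptor, was at 0 in all spleen and culture libraries but toxin control replicate 3, where it was at 2.82.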
